A study of Homo sapiens with 6 samples.

How the data were processed

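RNA came from activated human primary CD4+ T cells, grown from blood with interleukin 2 and stimulated for 48 hours on plates coated with antibodies to CD3 and CD28, per the labels' protocols. Total RNA was taken with RNeasy columns, turned into biotin-labelled sense-strand target with the Affymetrix whole-transcript assay, and hybridised to an exon array, per the labels' protocols and the probe annotation. Such an array carries many probe sets along each gene, so it reads both the level of a gene and the use of its parts. The 6 arrays fall into 3 groups of 2, named LL-sh4, shGFP and uninfected in the labels. The study is known to have used LL-sh4 as a short hairpin RNA (shRNA) against HNRNPLL, which encodes the RNA-binding protein hnRNP L-like. The shGFP group carried a control hairpin, and the uninfected group received no virus. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

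The authors deposited 1 value per probe set and array, for 272678 probe sets, on a natural log scale. The base is not stated and was read from the values. When repeated values were turned back to linear scale, up to 322 of them shared a fraction (rounded to 6 decimals) under the natural log, against 3 under log2 and 2 under log10. The array software, background correction, normalization and probe set summary that the authors used are not given in the sources used here. Deposited medians ran from 4.46 to 4.61 in natural log units, so the arrays had not been brought to 1 common distribution at this level. Between 0.935% and 1.64% of the values on an array stood at a floor, written as almost 0, and were set to 0.

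Deposited values were divided by the natural log of 2 and are called log2 levels from here on. The plan written before the data were examined took the deposited values as log2, or else as linear values with 1 added before log2. Neither applied to natural logs, so the conversion departs from that plan. No further normalization was applied in the main analysis, although the arrays differed in median and spread. Results after subtraction of array medians and after quantile normalization are given as alternatives. LL-sh4 replicate 2 and uninfected replicate 2 had the narrowest distributions, with interquartile ranges of 2.02 and 2.05 on the log2 scale against 2.41 to 2.52 on the other arrays.

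Probe sets were named through the platform's annotation, in which 251328 had 1 gene symbol, 8705 had several and 12645 had none. Of 16084 distinct symbols, 13843 were current in the reference gene table of assembly GRCh38.p14, 2126 were updated through a synonym and 115 were kept as given. Only probe sets with 1 symbol were used to describe genes. The 28 symbols on the Y chromosome or of the X-inactivation transcripts were left out of every step. No genome was used here and no table placed probe sets at exons, so probe sets are given by number and not by exon.

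Probe sets were kept when their mean over the 6 arrays reached the median over all probe sets, a log2 level of 6.55, which left 136339. A gene's level was the mean of its kept probe sets, and 9833 genes with at least 3 of them were tested. Group means were fitted with limma 3.58.1 in R 4.3.3 over all 6 arrays, and the 3 pairwise contrasts and an F test over the 3 groups were taken from that fit. The fit left 3 residual degrees of freedom, to which moderation added 12.5. Adjusted p-values are Benjamini-Hochberg values over all genes of a contrast, with a threshold of 0.05. All p-values are two-sided. The small number of arrays limits the precision of every value.

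The median gene had a log2 change of -0.18 in LL-sh4 against shGFP, -0.02 in LL-sh4 against uninfected and 0.20 in shGFP against uninfected. Fold changes are therefore given relative to the median gene of the contrast, while tests and counts used the values without this shift. After quantile normalization the medians were 0.01, -0.01 and 0.01.

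Exon usage was tested with diffSplice of limma in 9062 genes with at least 4 kept probe sets. It compares the change of a probe set with that of the other probe sets of its gene, and joins them into a Simes p per gene. The splicing index, the level of a probe set minus that of its gene on each array, was tested with limma as an alternative that uses the spread of each probe set. PTPRC, which encodes CD45, was followed in full because its splicing is the known subject of the study.

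The 24 gene lists were written before the data were examined. They cover T cell receptor and identity genes, T cell activation, naive and resting T cells, Th1 and cytotoxic genes, Th2, Th17 and regulatory T cells, interferon response, cell cycle, p53 response and apoptosis, NF-kB early response, heterogeneous nuclear ribonucleoproteins, SR proteins and other splicing factors, small RNA machinery, glycolysis, oxidative phosphorylation, cholesterol synthesis, endoplasmic reticulum stress, cytosolic ribosomal proteins, markers of B cells, of CD8 T and NK cells, of monocytes and dendritic cells and of erythroid cells and platelets, and transcripts known to be alternatively spliced in T cells. The 22 lists with at least 3 measured genes were tested with camera (limma) at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Members were counted as higher or lower over all genes and adjusted over the list alone.

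The genes named were chosen by a rule written before the data were examined. HNRNPLL and PTPRC are always given. Each gene-level contrast adds the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, filled to 20 by smallest p where fewer qualify. Each exon-usage contrast adds the 10 genes of smallest Simes p, and each list up to 4 members of smallest p. Alternatives written at the same time were subtraction of array medians, quantile normalization, no dim filter or one at the 75th percentile (8.04), the median in place of the mean of probe sets, the replicate number as a block, other moderation, other thresholds, fits of only the groups compared, the splicing index, and each array left out in turn. Leaving out both narrow arrays together was added after their distributions had been seen.

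Each step was tested on simulated data built from the shGFP means and the spread fitted over all 6 arrays. Known changes were added to the LL-sh4 arrays. With 67, 67 and 66 of 9833 genes changed 1.5-fold, 2-fold and 4-fold, limma recovered 11.9% of 1.5-fold, 59.7% of 2-fold and 100% of 4-fold changes and called 6 unchanged genes. In 9062 genes, diffSplice recovered 1.49%, 29.9% and 92.4% of such changes in 1 probe set and called 49 unchanged genes, and the splicing index recovered 0%, 1.49% and 95.5% and called 2. That simulation gave the probe sets of a gene a shared part of the noise. It replaced a first version with noise drawn for each probe set alone, in which diffSplice recovered 7.46%, 23.9% and 93.9% but called 523 unchanged genes, and the splicing index recovered 0% at every size and called 0. With no gene changed and shared noise, diffSplice called 30 genes in LL-sh4 against shGFP, 20 in LL-sh4 against uninfected and 21 in shGFP against uninfected, and the splicing index called 0 in each. Among simulated lists over the 9833 genes, camera called 0 of the 22 when nothing had changed. With the cell cycle list lowered 1.5-fold it gave that list an adjusted p of 2.1e-24, or 0.0396 with an estimated correlation. Genes were drawn independently there, while the correlation estimated within lists on the measured arrays ran from 0.42 (glycolysis) to 0.95 (Th17). The 0 calls therefore do not give the rate of false calls by camera in these data. The simulations for limma and diffSplice also gave every group the same spread and arrays of different groups no shared deviation. On the measured arrays the SD of replicate differences was 0.29 for LL-sh4, 0.11 for shGFP and 0.22 for uninfected cells. Replicate differences of LL-sh4 and uninfected cells correlated at 0.81. The unchanged genes called by limma and diffSplice therefore do not give rates of false calls in these data either.

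A few checks of explanations were revised after their first values had been seen, and both versions are given in the closing section. These are the test of neighbouring genes, first run with directions pooled and then within each direction, and the reading of the KLF2 target genes. The exon usage simulation was likewise replaced after its first result, the 523 false calls, had been seen. The 8 gene families described there were chosen after the largest changes had been seen.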

Results

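Levels of 9833 genes and of 136339 probe sets were read on 6 exon arrays of activated human primary CD4+ T cells. LL-sh4 cells, shGFP cells and uninfected cells were each measured on 2 arrays. Replicates correlated at 0.957 for LL-sh4, 0.994 for shGFP and 0.973 for uninfected cells (Pearson's r across genes, which are not independent replicates). LL-sh4 arrays correlated with the arrays of the other groups at 0.832 to 0.884. The standard deviation over genes of the difference between replicates was 0.29 on the log2 scale for LL-sh4, 0.11 for shGFP and 0.22 for uninfected cells. Values below are limma estimates with n = 2 arrays per group, and fold changes are relative to the median gene.

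The first question was whether HNRNPLL, the gene that the LL-sh4 hairpin is known to be directed against, was lower in LL-sh4 cells. HNRNPLL stood at log2 levels of 7.96 and 7.35 on the LL-sh4 arrays, 8.97 and 9.02 on the shGFP arrays, and 8.70 and 8.30 on the uninfected arrays. Relative to the median gene it fell by 1.16 on the log2 scale against shGFP (SE 0.22, limma adjusted p = 0.00072), which left 44.9% of the shGFP level. Against uninfected cells the log2 change was -0.82 (SE 0.22, adjusted p = 0.016), or 56.5% remaining. The shGFP and uninfected cells differed by 0.29 (adjusted p = 0.38). Of the 15 HNRNPLL probe sets on the array, 13 were lower in LL-sh4 than in shGFP cells, while probe set 2548933 had a mean level of 8.27 in LL-sh4, 7.89 in shGFP and 7.60 in uninfected cells. The fall against uninfected cells did not pass the threshold without uninfected replicate 1 (-0.74, adjusted p = 0.059), without the dim filter (-0.72, adjusted p = 0.092) or with the median of the probe sets (-0.26, adjusted p = 0.58). Without moderation of the variance neither fall passed (adjusted p = 0.14 against shGFP and 0.25 against uninfected).

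**Figure D1:**
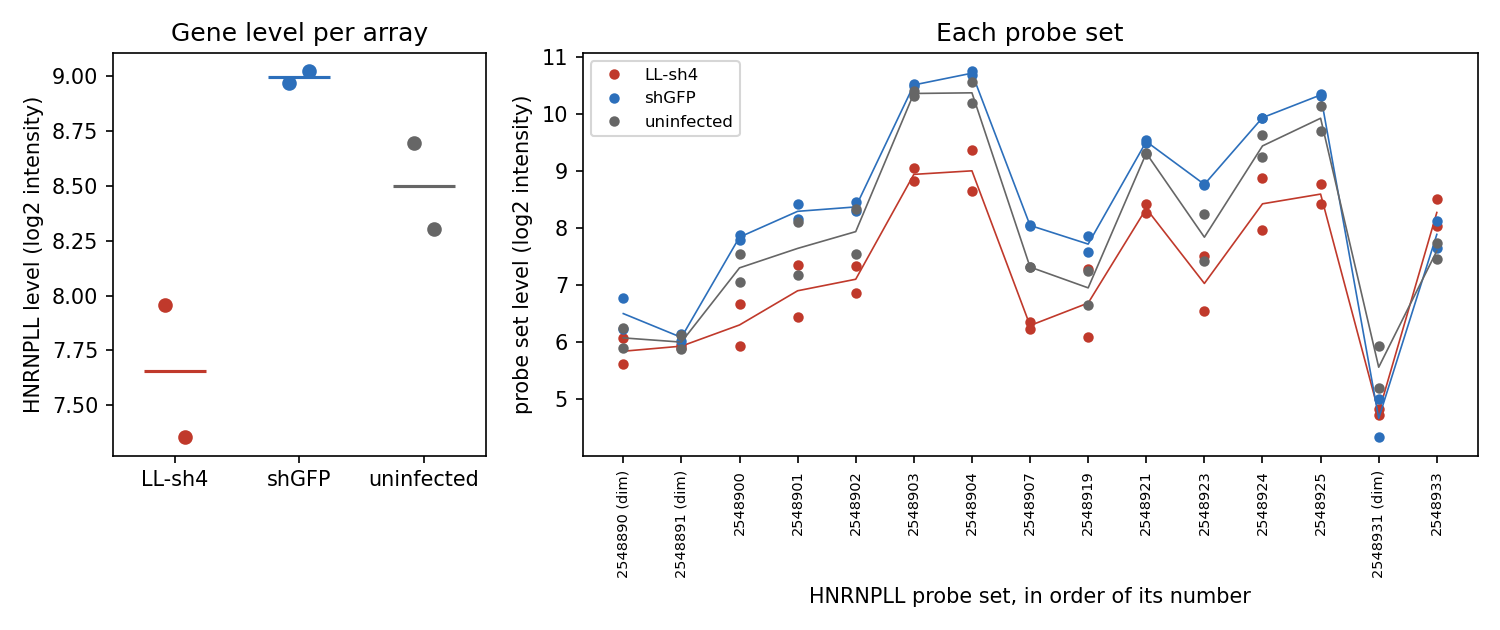
HNRNPLL levels (log2 intensity) on each of the 6 arrays, with points for arrays and bars for group means in the left panel, and each of its 15 probe sets in order of number in the right panel, with points for arrays and lines through group means. The LL-sh4 arrays lie at 7.96 and 7.35, below the 4 other arrays, and 13 of the 15 probe sets have a lower mean in LL-sh4 than in shGFP cells.

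LL-sh4 cells were then compared with shGFP cells, which carried a control hairpin. The largest rise was that of CCL1, a chemokine, with a relative log2 change of 5.01 (SE 0.22, adjusted p = 5.6e-09). TNFAIP2, a TNF-induced gene, rose by 3.60 (SE 0.19), the actin-bundling gene FSCN1 by 3.32 (SE 0.19) and EBI3, the subunit shared by interleukins 27 and 35, by 3.32 (SE 0.19). CSF2 (GM-CSF) rose by 2.82, CD83 by 2.79, IL13 by 2.72, the interleukin 3 receptor gene IL3RA by 2.61 and TNFSF4 (OX40 ligand) by 2.59, and RASSF4 rose by 3.05. FSCN1, EBI3 and CD83 are also genes of mature dendritic cells, and the measured monocyte and dendritic cell markers had a median of 0.33. KLF2, a transcription factor of resting T cells, fell by 3.32 (SE 0.20, adjusted p = 3.7e-08), to a mean level of 5.73 against 9.23 in shGFP cells. The other large falls were those of RASA3 (-2.35), UHRF1 (-2.01), the linker histone gene H1-1 (-1.98), CDCA8 (-1.70), E2F2 (-1.70), IGHM (-1.65), CDCA7 (-1.63), FAM111B (-1.61) and E2F8 (-1.59), with adjusted p-values of at most 9.3e-05. In shGFP cells the mean levels of CCL1 (6.37), TNFAIP2 (5.80) and RASSF4 (6.20), and in LL-sh4 cells those of KLF2, RASA3 (6.35) and IGHM (6.05), lay under the dim threshold of 6.55.

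**Figure D2:**
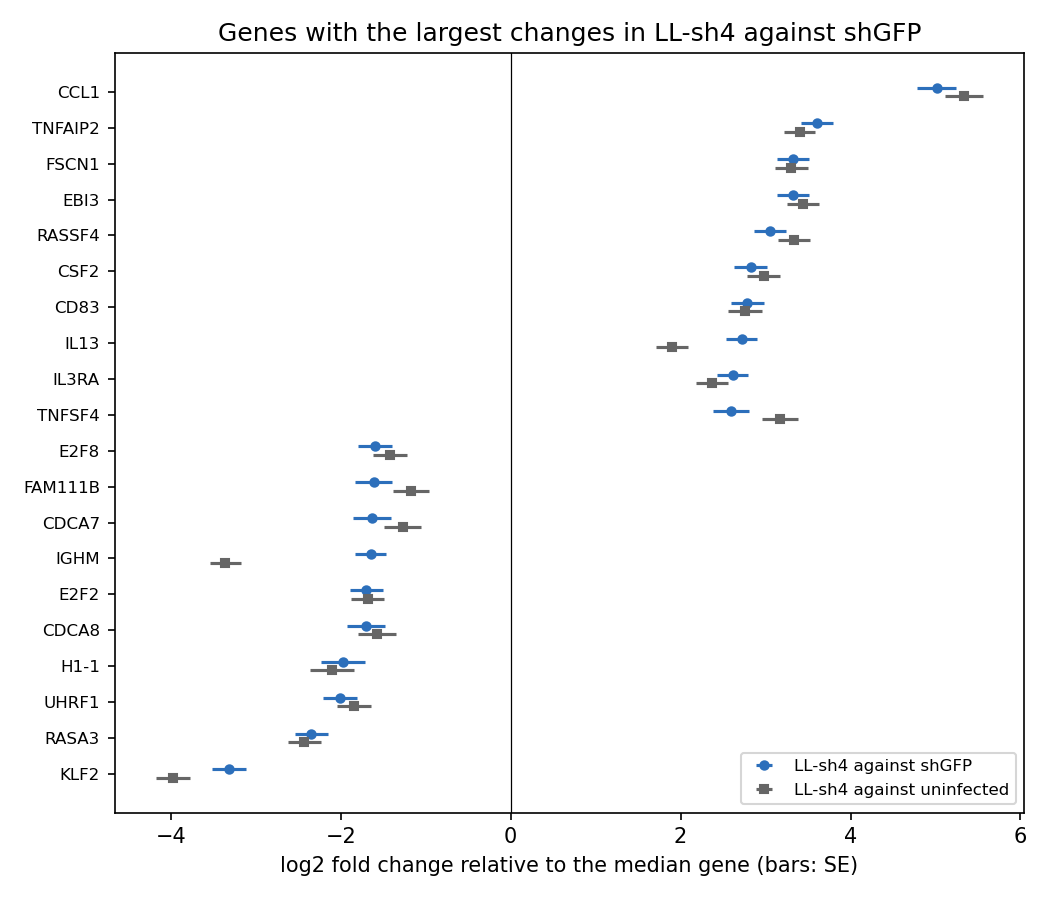
Log2 fold change relative to the median gene (horizontal axis) of the 10 largest rises and 10 largest falls in LL-sh4 against shGFP (circles), with the same genes against uninfected cells (squares), where bars are the SE and n = 2 arrays per group. CCL1 lies at 5.01 and 5.33, and KLF2 at -3.32 and -3.98.

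In this comparison 523 genes were higher and 1698 lower in LL-sh4 cells, 2221 in all, of which 254 and 248 had a relative change of at least 2-fold. The groups did not overlap in 66.2% of genes, or 74.3% once the median of all genes was subtracted from each array, where chance gives 33.3%. Genes of an array shift together, so the excess over chance is not a test of single genes here or in the contrasts below. The split depended on scaling. It was 1943 higher and 2303 lower after quantile normalization, and 1238 higher and 2267 lower after subtraction of array medians. It was 398 higher and 745 lower without the dim filter (1143 in all), 53 and 43 without moderation of the variance (96 in all), and 2456 and 3392 without both narrow arrays (5848 in all). It was 862 higher and 1121 lower without LL-sh4 replicate 2. The count was 4473 without LL-sh4 replicate 1, 798 without shGFP replicate 1 and 779 without shGFP replicate 2.

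The list of cell cycle genes moved as a whole. All 27 measured members fell (27 adjusted over the list alone), with a median relative change of -1.14 and camera adjusted p = 1.4e-16, or adjusted p = 0.69 with an estimated correlation. AURKB, a mitotic kinase, changed by -1.45, the checkpoint kinase gene BUB1B by -1.41, the ribonucleotide reductase gene RRM2 by -1.29 and the replication licensing gene MCM2 by -1.19. In the list of p53 response and apoptosis genes 12 of 21 members rose (14 adjusted over the list alone) and 0 fell at an adjusted p under 0.05 in limma, with camera adjusted p = 1.3e-12 and adjusted p = 0.69 with an estimated correlation. CDKN1A, the inhibitor p21 of cyclin-dependent kinases, rose by 2.10, ZMAT3 by 1.54 and TP53I3 by 1.36.

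Lists of activation and effector genes were compared next. In the NF-kB early response list 10 of 15 members rose (11 adjusted over the list alone), with a median of 1.11 and camera adjusted p = 2.0e-12, or adjusted p = 0.69 with an estimated correlation. CD83 is among them, with the adhesion gene ICAM1 at 2.10, IER3 at 1.56 and the apoptosis inhibitor gene BIRC3 at 1.41. In the T cell activation list 8 of 19 members rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 6.7e-08, adjusted p = 0.69 with an estimated correlation), among them the costimulatory receptor genes TNFRSF18 (2.34), TNFRSF4 (1.67) and TNFRSF9 (1.43). Of 10 Th17 genes 6 rose (8 adjusted over the list alone), with CCL20 at 2.50, IL22 at 2.20, IL17F at 1.43 and IL17A at 1.16. Of 15 Th1 and cytotoxic genes 6 rose (6 adjusted over the list alone), with CCL5 at 1.80, IFNG at 1.75, FASLG at 1.41 and the perforin gene PRF1 at 1.21. The camera adjusted p was 5.8e-09 for the Th17 list and 3.6e-06 for the Th1 list, and the adjusted p was 0.69 for both with an estimated correlation. Of 5 Th2 genes IL13 rose (2 adjusted over the list alone, the second being IL17RB at 0.74; camera adjusted p = 0.0027, adjusted p = 0.71 with an estimated correlation). Of 7 regulatory T cell genes TIGIT (0.83) and IL2RB (0.74) rose (2 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.76 with an estimated correlation). Of 21 interferon response genes 4 rose (4 adjusted over the list alone; camera adjusted p = 5.3e-05, adjusted p = 0.76 with an estimated correlation), namely IFIT2 (1.01), RSAD2 (0.96), ISG15 (0.88) and IRF7 (0.88). Quantile normalization gave 14 higher interferon response genes, 4 Th2 genes and 5 regulatory T cell genes, and subtraction of array medians 8, 3 and 4.

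The naive and resting T cell list held members that moved apart. TCF7 (1.51), IL7R (1.67) and CCR7 (1.29) were among 6 of 16 that rose, while KLF2 was 1 of 2 that fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.80 with an estimated correlation). Of 17 T cell receptor and identity genes 2 rose, CD2 (0.91) and CD6 (0.85), and 3 fell, LCK (-0.53) and SIT1 (-0.41) among them (3 and 5 adjusted over the list alone; camera adjusted p = 0.13, adjusted p = 0.88 with an estimated correlation), and quantile normalization gave 8 higher and 4 lower. The call of the naive list was lost when any of the 6 arrays was left out (adjusted p from 0.0999 to 0.136) after quantile normalization (adjusted p = 0.057), without both narrow arrays (0.057) and without the dim filter (0.082). The call of the regulatory T cell list was lost without LL-sh4 replicate 1 (adjusted p = 0.062), without shGFP replicate 1 (0.058), without the dim filter (0.060) and without moderation (0.13). LCK, CD2, CD6, SIT1, TIGIT, IL2RB and the 4 interferon response genes were among 27 named genes that no longer passed the threshold in this contrast without shGFP replicate 1, and also among 27 without shGFP replicate 2. SIT1 also did not pass without LL-sh4 replicate 2.

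Of 24 measured genes for heterogeneous nuclear ribonucleoproteins, the RNA-binding proteins to which hnRNP L-like belongs, 15 fell and 0 rose in limma (17 and 0 adjusted over the list alone), with a median of -0.39 and camera adjusted p = 4.6e-05, or adjusted p = 0.76 with an estimated correlation. HNRNPA3 changed by -1.30, HNRNPR by -0.86, HNRNPAB by -0.72 and HNRNPUL1 by -0.67. Of 32 SR proteins and other splicing factors 8 fell (8 adjusted over the list alone), among them SFPQ (-0.69), SRSF1 (-0.61), SRSF2 (-0.59) and PRPF8 (-0.56), with camera adjusted p = 0.072 and adjusted p = 0.88 with an estimated correlation. After quantile normalization 2 members of that list were higher and 12 lower. Of 11 small RNA machinery genes PRKRA (-0.68) and DROSHA (-0.51) fell (2 adjusted over the list alone; camera adjusted p = 0.39), and after quantile normalization 3 members were higher and 4 lower. HNRNPUL1, these 4 splicing factors, PRKRA and DROSHA no longer passed without shGFP replicate 1, nor without shGFP replicate 2, HNRNPAB did not pass without shGFP replicate 1, and DROSHA did not pass without LL-sh4 replicate 2.

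Of 24 oxidative phosphorylation genes 5 fell (9 adjusted over the list alone), with UQCRC2 at -0.93 and NDUFA9 at -0.58, and 11 were lower after quantile normalization and 10 after subtraction of array medians. The camera adjusted p was 0.026, the adjusted p was 0.88 with an estimated correlation, and the call was lost when any of the 6 arrays was left out (adjusted p from 0.054 to 0.13), with the 75th percentile filter (0.053) and without moderation (0.13). In glycolysis ALDOC (1.32) and PFKFB3 (0.93) were among 3 of 19 that rose and HK2 (-0.86) and PFKP (-0.76) among 5 that fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.97), with a median of -0.0042 and a mean of 0.030, and each of the 2 scalings gave 5 higher and 8 lower. Of 17 cholesterol synthesis genes MVK (-0.87) fell (1 adjusted over the list alone; camera adjusted p = 0.39), and 7 members were higher and 2 lower after quantile normalization. In the endoplasmic reticulum stress list ATF3 (1.04) rose and ASNS (-0.84), TRIB3 (-0.71) and XBP1 (-0.55) fell, of 15 (1 and 3 adjusted over the list alone; camera adjusted p = 0.50), with 2 higher and 4 lower after quantile normalization. Of 17 cytosolic ribosomal protein genes 0 passed in limma (0 adjusted over the list alone; camera adjusted p = 0.40), with RPS19 at 0.65 (unadjusted p = 0.020), and 1 was higher under each of the 2 scalings. Of the transcripts known to be alternatively spliced in T cells 5 of 24 rose in level and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.026, adjusted p = 0.88 with an estimated correlation). IL7R (1.67), BCL2L1 (1.16) and CD44 (1.10) rose and ITGA6 (-1.06) fell. PFKFB3, NDUFA9, ATF3 and XBP1 no longer passed without shGFP replicate 1, nor without shGFP replicate 2, and TRIB3 did not pass without shGFP replicate 2. The call of the spliced transcripts was lost without LL-sh4 replicate 1 (adjusted p = 0.096), without shGFP replicate 1 (0.058), without the dim filter (0.23) and without moderation (0.085).

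Of the markers of other blood cells, 2 of 10 for B cells, 5 of 14 for CD8 T and NK cells, 5 of 14 for monocytes and dendritic cells and 1 of 9 for erythroid cells and platelets had enough probe sets above the dim threshold to be tested. Of 5 measured CD8 T and NK cell markers GNLY (1.36) and KLRD1 (0.88) rose and CD8B (-0.38) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.12). Of 5 monocyte and dendritic cell markers VCAN (1.67) rose and AIF1 (-0.56) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.12), with 3 higher and 1 lower after quantile normalization. The 2 measured B cell markers, CD79B at 0.04 and CD22 at 0.23, and the 1 platelet marker, ITGA2B at 0.40, did not pass in limma (unadjusted p = 0.46, 0.79 and 0.31), nor adjusted over the list alone, and lists of fewer than 3 genes were not tested as sets. KLRD1, CD8B and AIF1 no longer passed without shGFP replicate 1, nor without shGFP replicate 2, CD8B also not without LL-sh4 replicate 2 and KLRD1 not without LL-sh4 replicate 1.

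**Figure D3:**
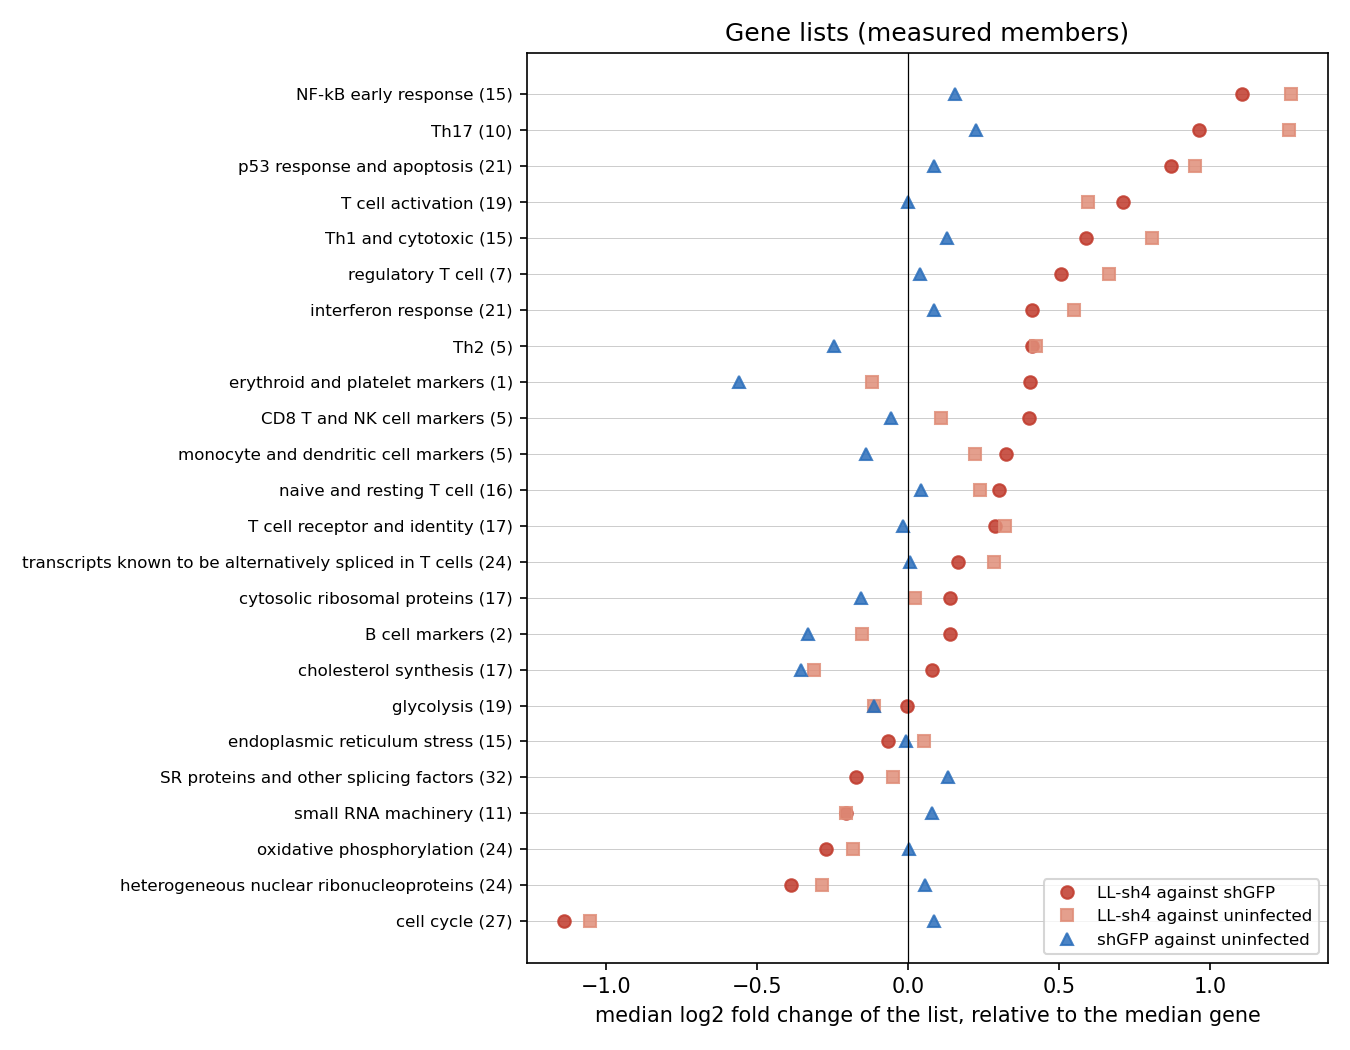
Median log2 fold change of the measured members of each of the 24 gene lists, relative to the median gene (horizontal axis), for LL-sh4 against shGFP (circles), LL-sh4 against uninfected (squares) and shGFP against uninfected (triangles), with the number of measured members in brackets. The cell cycle list has the lowest median in LL-sh4 against shGFP (-1.14) and the NF-kB early response list the highest (1.11).

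LL-sh4 cells were next compared with uninfected cells. CCL1 rose by 5.33 (SE 0.22, adjusted p = 1.3e-09), EBI3 by 3.44, TNFAIP2 by 3.40, RASSF4 by 3.34, FSCN1 by 3.30, TNFSF4 by 3.17, CSF2 by 2.98, CHN1 by 2.89, CD83 by 2.76 and TCF7, a transcription factor of naive and memory T cells, by 2.74. KLF2 fell by 3.98 (SE 0.20, adjusted p = 7.9e-09) and IGHM, the immunoglobulin mu heavy chain gene, by 3.36 (SE 0.19, adjusted p = 1.5e-08). The serine synthesis genes PHGDH (-2.46) and PSAT1 (-2.12) and the arginine synthesis gene ASS1 (-2.12) fell, with RASA3 (-2.43), H1-1 (-2.10), RBM38 (-1.90), RAP1GAP2 (-1.89) and UHRF1 (-1.85). IGHM had mean levels of 6.05 in LL-sh4, 7.88 in shGFP and 9.42 in uninfected cells, while the B cell markers CD79B (-0.52, adjusted p = 0.056) and CD22 (0.21, adjusted p = 0.55) did not pass over all genes, and 1 of these 2 was lower adjusted over the list alone. In uninfected cells the mean levels of CCL1 (5.88), TNFAIP2 (5.84), RASSF4 (5.75) and TNFSF4 (6.51), and in LL-sh4 cells those of KLF2 (5.73), IGHM, RASA3 (6.35), ASS1 (6.31) and RAP1GAP2 (6.13), lay under the dim threshold of 6.55.

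Against uninfected cells 897 genes were higher and 895 lower, 1792 in all, of which 308 and 215 had a relative change of at least 2-fold. The groups did not overlap in 46.6% of genes, or 67.6% with array medians over genes subtracted, where chance gives 33.3%. The direction of the split depended on single arrays. It was 738 higher and 1880 lower without LL-sh4 replicate 1, 1902 and 823 without LL-sh4 replicate 2 (2725 in all), 1148 and 465 without uninfected replicate 1, and 541 and 1231 without uninfected replicate 2. LL-sh4 replicate 2 and uninfected replicate 2 departed from replicate 1 in the same way (r = 0.81 across genes, which are not independent). Quantile normalization gave 2118 higher and 2235 lower, and subtraction of array medians 1508 and 1832. The count was 1016 (508 each way) without the dim filter, 180 (109 and 71) without moderation and 5612 without both narrow arrays.

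The gene lists called in this contrast were 12, of which 10 were higher and 2 lower, and with an estimated correlation 0 were called (adjusted p from 0.64 to 0.86 for these lists). Cell cycle genes fell in 25 of 27 (25 adjusted over the list alone), with AURKB at -1.50, CDC20 at -1.45, MCM2 at -1.30 and PLK1 at -1.28. Of 21 genes of the p53 response and apoptosis 16 rose (17 adjusted over the list alone), with CDKN1A at 2.33, TP53I3 at 1.76, SESN1 at 1.71 and ZMAT3 at 1.45. Of 15 NF-kB early response genes 12 rose (13 adjusted over the list alone), with ICAM1 at 2.49, BIRC3 at 2.01 and IER3 at 1.78. The camera adjusted p was 1.7e-16, 2.0e-13 and 1.5e-13 for these lists, and the adjusted p was 0.64 for each with an estimated correlation. Th17 genes rose in 8 of 10 (8 adjusted over the list alone), with CCL20 at 2.57, IL22 at 2.45 and RORA at 1.34, and Th1 and cytotoxic genes in 9 of 15 (9 adjusted over the list alone), with IFNG at 2.39 and the granzyme gene GZMB at 1.06. The camera adjusted p was 1.5e-09 and 1.0e-07, and the adjusted p was 0.64 for both with an estimated correlation. In T cell activation 9 of 19 rose and 3 fell (11 and 3 adjusted over the list alone), in interferon response 7 of 21 rose (13 adjusted over the list alone), with IFI27 at 1.89 and RSAD2 at 1.18, and in regulatory T cells 4 of 7 rose (5 adjusted over the list alone). Their camera adjusted p was 3.6e-05, 2.5e-05 and 0.0044, and the adjusted p was 0.83 for each with an estimated correlation. Heterogeneous nuclear ribonucleoprotein genes fell in 4 of 24 (4 adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.86 with an estimated correlation), with HNRNPA3 at -1.36, and 11 were lower under quantile normalization and also under subtraction of array medians. In the naive and resting list 6 of 16 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.024, adjusted p = 0.86 with an estimated correlation), a call that was lost in 5 of the 6 fits with an array left out (adjusted p from 0.053 to 0.11), all but the one without LL-sh4 replicate 1, and without both narrow arrays (0.079). The Th2 list (1 of 5 rose, 1 adjusted over the list alone, camera adjusted p = 0.029) and the spliced transcripts (6 of 24 rose, 6 adjusted over the list alone, camera adjusted p = 0.0075) had adjusted p of 0.83 and 0.86 with an estimated correlation. The Th2 call was lost with the 75th percentile filter (adjusted p = 0.073) and that of the regulatory T cell list without moderation (adjusted p = 0.064). Quantile normalization gave 16 higher interferon response genes, 3 Th2 genes and 11 spliced transcripts (1 lower), and subtraction of array medians 12, 3 and 8 (1 lower).

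The 10 other lists tested were not called against uninfected cells (camera adjusted p from 0.062 for oxidative phosphorylation to 0.77 for ribosomal proteins). CD2 (1.25), CD6 (0.85) and CD7 (0.79) rose and CD28 (-0.72) was 1 of 3 that fell among 17 T cell identity genes (3 and 3 adjusted over the list alone). RBFOX2 (0.80) rose and PRPF8 (-0.66) and SRSF4 (-0.62) fell among 32 splicing factors (1 and 1 adjusted over the list alone), and PRKRA (-0.71) fell among 11 small RNA genes (1 adjusted over the list alone). In glycolysis 4 of 19 rose and 4 fell (4 and 4 adjusted over the list alone), with PFKFB3 at 1.43 and HK2 at -1.51, and in oxidative phosphorylation 3 of 24 fell (3 adjusted over the list alone). MVK (-0.98) and FDPS (-0.67) fell among 17 cholesterol genes (2 higher and 5 lower adjusted over the list alone), and ATF3 (1.18) rose and ASNS (-1.15) and TRIB3 (-1.01) fell among 15 endoplasmic reticulum stress genes (1 and 2 adjusted over the list alone), a list with a median of 0.05 and a mean of -0.06. RPS19 (0.68) rose among 17 ribosomal protein genes (1 adjusted over the list alone). GNLY (1.34) and KLRD1 (0.88) rose and NCR3 (-0.96) fell among 5 CD8 T and NK cell markers (2 and 1 adjusted over the list alone), VCAN (1.62) rose among 5 monocyte and dendritic cell markers (2 and 1 adjusted over the list alone), and the platelet marker ITGA2B stood at -0.12 (adjusted p = 0.72). Quantile normalization gave 9 higher and 4 lower T cell identity genes, 8 and 7 splicing factors, 3 and 3 small RNA genes, 3 and 8 cholesterol genes, 1 and 8 oxidative phosphorylation genes, 5 and 7 glycolysis genes, 3 and 5 endoplasmic reticulum stress genes, 3 and 1 monocyte and dendritic cell markers, and 2 and 2 CD8 T and NK cell markers. CD28, PRPF8, SRSF4, PRKRA and FDPS no longer passed without uninfected replicate 1, PRPF8, SRSF4, FDPS and RPS19 without either shGFP array, SRSF4 and PRKRA without LL-sh4 replicate 2, and RPS19 without uninfected replicate 2.

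Genes that passed in the same direction against both controls numbered 1246, of which 450 were higher and 796 lower, and 0 limma calls went in opposite directions. Independent lists of these sizes would share 202 genes, 47.7 higher and 155 lower. In 100 draws of simulated noise with all groups unchanged, 0 genes were shared in each. No measured control values entered these draws, so their 0 does not give the overlap expected from shared LL-sh4 arrays. The comparisons share the LL-sh4 arrays, so part of the excess over independent lists may come from those arrays. The F test over the 3 groups called 2103 genes. Without LL-sh4 replicate 1 these counts were 2217 genes against both controls and 4627 in the F test, without shGFP replicate 1 they were 623 and 1276, and without shGFP replicate 2 they were 606 and 1251. The counts were 685 and 880 without the dim filter, 85 and 38 without moderation, 3327 and 4592 after quantile normalization, 2532 and 3513 with array medians subtracted, and 4528 and 6638 without both narrow arrays, and with the median of probe sets 825 passed against both controls. The F test called 3300 without LL-sh4 replicate 2 and 3545 without uninfected replicate 1.

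The controls were then compared with each other, to see how cells with a control hairpin differed from cells that were not infected. IFI27, an interferon-induced gene, rose by 1.33 (SE 0.19, adjusted p = 0.0024) in shGFP against uninfected cells, TCF7 by 1.19, GPR84 by 1.15, CHRNA6 by 1.08 and PTPN3 by 0.96. IGHM (-1.75, SE 0.19, adjusted p = 0.0024) and ASS1 (-1.70, SE 0.19, adjusted p = 0.0024) fell. These 7 were the genes past the threshold, while 1266 had an unadjusted p under 0.05. The groups did not overlap in 63.3% of genes, or 66.1% with array medians over genes subtracted, where chance gives 33.3%. Quantile normalization gave 45 higher and 74 lower and subtraction of array medians 10 and 17. The limma count was 0 without the dim filter (1519 with an unadjusted p under 0.05) and 0 without moderation (660 with an unadjusted p under 0.05), 3 with the median of probe sets, 29 with trend and robust moderation and 1916 without both narrow arrays. The count was 793 (675 higher and 118 lower) without LL-sh4 replicate 1 and also without LL-sh4 replicate 2, 499 (441 and 58) without uninfected replicate 1 and 11 (5 and 6) without uninfected replicate 2. CHRNA6 and PTPN3 did not pass without shGFP replicate 1, nor without shGFP replicate 2. The genes next in p, given as values, included the chemokine gene CXCL10 (0.99, adjusted p = 0.052), CYB5R3 (-1.21, 0.052), CDH3 (0.84, 0.052) and PHGDH (-1.14, 0.089).

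Between the controls 3 lists were called by camera and 0 with an estimated correlation, while without the dim filter camera called 15 (12 higher and 3 lower) and without moderation 5 (2 and 3). Without LL-sh4 replicate 1, LL-sh4 replicate 2, shGFP replicate 1 or shGFP replicate 2 it called 2, and without uninfected replicate 1 it called 1. The NF-kB early response list was higher (median 0.16, adjusted p = 0.0076), the SR protein list was higher (median 0.13, adjusted p = 0.046) and the cholesterol synthesis list was lower (median -0.36, adjusted p = 2.8e-06), each with an adjusted p of 0.997 with an estimated correlation. No single member of these 3 lists passed over all genes in limma (2, 0 and 0 adjusted over the list alone). TCF7 in the naive list and IFI27 in the interferon list were the members of any list past the threshold over all genes. Adjusted over the list alone, 4 Th1 and cytotoxic genes, 4 p53 response genes, 3 Th17 genes, 1 cell cycle gene and 1 spliced transcript were higher, and 2 activation genes, 1 Th2 gene and 1 CD8 T or NK cell marker were lower. The activation and oxidative phosphorylation lists had medians above 0 (0.0013 and 0.0031) and means below 0 (-0.12 and -0.00022), and the T cell identity list had both below 0 (-0.02 and -0.03) with the test upward (adjusted p = 0.95). The call of the SR protein list was lost when any of the 6 arrays was left out (adjusted p from 0.067 to 0.12), with the 75th percentile filter (0.15), with the median of probe sets (0.062) and without moderation (0.23), and that of the NF-kB list without uninfected replicate 1 (adjusted p = 0.090).

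The use of gene parts was compared next, beginning with PTPRC, for which 41 probe sets were kept. At the level of the whole gene PTPRC differed by -0.32 (SE 0.22, adjusted p = 0.12) between LL-sh4 and shGFP and by -0.28 (adjusted p = 0.41) between LL-sh4 and uninfected cells. Within the gene, probe set 2373878 was used more in LL-sh4 cells, by 3.46 on the log2 scale against shGFP (diffSplice adjusted p = 2.8e-12) and by 3.49 against uninfected cells (adjusted p = 1.5e-12). Its mean level was 9.94 in LL-sh4 (SD 0.81), 7.07 in shGFP (SD 0.11) and 6.83 in uninfected cells (SD 0.29), with n = 2 each. Probe set 2373882 was used more by 2.71 (adjusted p = 3.8e-08) and 2.23 (adjusted p = 2.4e-05), with mean levels of 11.4, 9.21 and 9.48. With the splicing index, probe set 2373878 passed against both controls (adjusted p = 0.0020 and 0.0016) and probe set 2373882 did not (adjusted p = 0.060 and 0.096). Adjusted over the probe sets of PTPRC alone, probe set 2373879 also passed against shGFP (1.15, adjusted p = 0.024). Between shGFP and uninfected cells 0 of the 41 probe sets passed with diffSplice and 0 with the splicing index, and the smallest unadjusted p was 0.035.

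**Figure D4:**
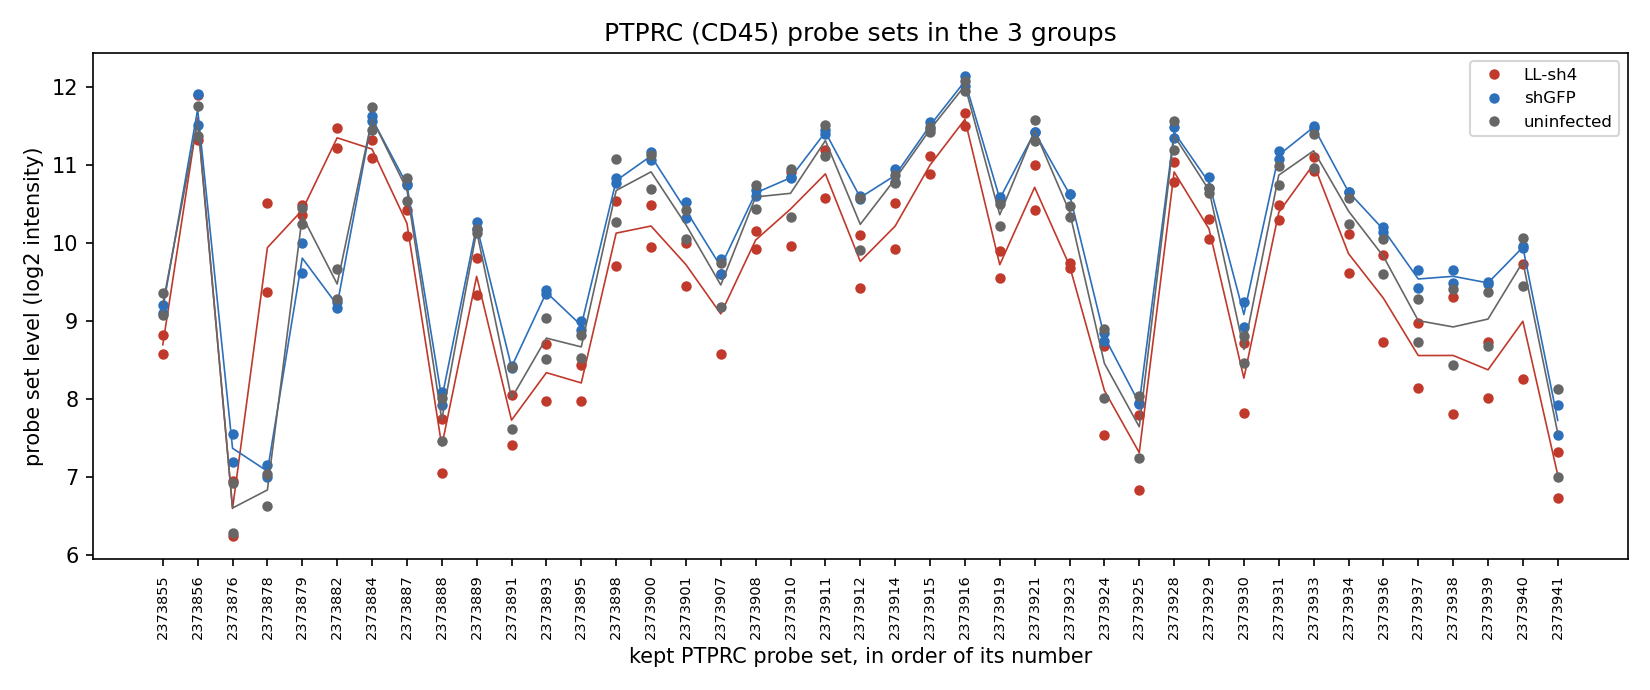
Levels (log2 intensity) of the 41 kept PTPRC probe sets in order of number, with a point for each of the 6 arrays and lines through the group means. At probe set 2373878 the LL-sh4 mean is 9.94 against 7.07 in shGFP and 6.83 in uninfected cells, and at probe set 2373882 it is 11.4 against 9.21 and 9.48.

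Across 9062 genes, diffSplice called changed usage in 296 genes in LL-sh4 against shGFP, with 251 probe sets used more and 64 used less. In data simulated with no change and with noise shared within a gene it called 30 genes in this contrast, and 49 unchanged genes when others had changed, while with noise drawn for each probe set alone it called 523. The simulations lacked the unequal spreads and shared deviations of the measured arrays. Their counts are therefore not rates of false calls here or in the contrasts below. The genes of smallest p were ATP8B3, ZFPM1, PTPRC, RAP1GAP2, OPN3, FARP2, SIGIRR, H2AC6, TXNDC5 and DOCK3. In ATP8B3, probe set 3845469 was used more by 4.67 (adjusted p = 3.0e-13), with a mean level of 9.76 in LL-sh4 and 6.36 in shGFP cells, and in ZFPM1, which encodes a partner of GATA factors, probe set 3673467 was used more by 3.99 (12.1 against 7.51). In the same direction went 1 probe set of FARP2 (4.07), of the histone gene H2AC6 (3.79), of OPN3 (3.65), of TXNDC5 (3.21), of SIGIRR (3.03) and of DOCK3 (2.59). In RAP1GAP2, probe set 3706528 was used less (-3.38), at a level of 3.82 against 8.73. The splicing index called 31 genes, of which 30 were also called by diffSplice. The diffSplice count was 67 without shGFP replicate 1, 71 without shGFP replicate 2 and 1002 without LL-sh4 replicate 1, and 557 after quantile normalization. It was 2500 without the dim filter, 73 with the 75th percentile filter and 144 among genes above the median level, of fewer tested in both of these. Without LL-sh4 replicate 2 there were 104 probe sets used more and 110 used less, and without both narrow arrays 1042 and 926.

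Against uninfected cells diffSplice called 232 genes (131 probe sets used more, 146 less) and the splicing index 41, all of which diffSplice also called. With no change simulated diffSplice called 20. The count was 2062 without the dim filter, 560 after quantile normalization, 56 with the 75th percentile filter and 142 among genes above the median level. ATP8B3 (3.95), DOCK3 (2.95), FARP2 (4.47), H2AC6 (3.85), OPN3 (3.25) and ZFPM1 (3.84) again had a probe set used more, and RAP1GAP2 had one used less (-3.79). TNFAIP2 and TCF7, which rose as genes (3.40 and 2.74), each had a probe set used less (-2.85 and -2.40). These probe sets themselves rose, but less than their genes, with mean levels of 7.73 in LL-sh4 against 6.96 in uninfected cells for TNFAIP2. For TCF7 the levels were 8.65 and 8.18. The count was 92 without shGFP replicate 1 and also without shGFP replicate 2, 548 without LL-sh4 replicate 2 and 121 without uninfected replicate 2. The split also turned, with 191 probe sets used more and 135 less without LL-sh4 replicate 1, 178 and 416 without LL-sh4 replicate 2, 86 and 30 without uninfected replicate 2, 31 and 21 with the 75th percentile filter, and 1253 and 1162 without both narrow arrays.

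Between shGFP and uninfected cells diffSplice called 78 genes (12 probe sets used more, 66 less), while the splicing index called 0, with 449 genes at an unadjusted p under 0.05. With no change simulated diffSplice called 21. The count was 2366 without the dim filter, 220 after quantile normalization, 8 with the 75th percentile filter and 48 among genes above the median level. The genes of smallest p were EDC4 (-1.73), RBCK1 (-2.62), TCF7 (1.96), JAG2 (-2.63), KHSRP (-2.29), ESRRA (-3.80), IFNGR2 (-2.96), ACTG1 (1.44), SMUG1 (-2.65) and MAP2K3 (-2.47). The called probe sets varied more within groups than others, with a median SD of 0.64 against 0.25 for all probe sets. The count was 25 without shGFP replicate 1, 29 without shGFP replicate 2, 239 without uninfected replicate 1, 12 without uninfected replicate 2, and 225 without LL-sh4 replicate 1 or without LL-sh4 replicate 2. The split was 8 probe sets used more and 4 less without uninfected replicate 2, 5 and 4 with the 75th percentile filter, and 210 and 192 without both narrow arrays.

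Of the 24 transcripts known to be alternatively spliced in T cells, PTPRC and STAT5A (a probe set used more by 1.05, gene adjusted p = 0.026) passed in LL-sh4 against shGFP, and CD44 passed adjusted over the list alone (0.99, adjusted p = 0.018 over the list alone). Against uninfected cells PTPRC, CD44 (1.43, gene adjusted p = 0.00035) and STAT5A (1.38, gene adjusted p = 0.00044) passed, and the same number passed adjusted over the list alone. Between the controls 0 passed with diffSplice or the splicing index, and 1, PKM, had an unadjusted diffSplice p under 0.05 (0.032). With the splicing index PTPRC was the only one to pass in either LL-sh4 contrast. Without shGFP replicate 1, and also without shGFP replicate 2, 1 gene of the list passed against shGFP, and without uninfected replicate 1 there was 1 between the controls.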

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

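The tests chosen only after the result was seen were the comparison of neighbouring genes within each direction, the spread of probe sets called between the controls, the dendritic cell and monocyte transcripts, the 10 largest rises without the narrow arrays, and the replicate differences after quantile normalization.

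Probe sets that the annotation gives to several genes or to none were outside the comparisons, and they drew attention because some differed between LL-sh4 and shGFP cells while 0 of either kind passed between the controls in limma (304 and 424 had an unadjusted p under 0.05). The same holds for probe sets with 1 symbol, of which 0 of 126799 passed between the controls (11339 with an unadjusted p under 0.05). Of 4103 kept probe sets with several gene symbols 260 passed the threshold (79 higher and 181 lower), or 6.34%. Of 5254 with no symbol 161 passed (28 higher and 133 lower), or 3.06%. Among probe sets with 1 symbol the share was 5.94%.

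In the first pattern weighed, the change of exon usage in 296 genes between LL-sh4 and shGFP cells, dim probe sets that cannot follow a change of their gene were argued against as the whole source, because 23.2% of the 315 called probe sets (exact 95% interval 18.6% to 28.2%) lay below their gene and opposite to its change, under the share of more than 50% that this source needs. They may still account for part, since usage changed in 2500 genes without the dim filter and in 73 with the 75th percentile filter (of fewer tested), and since 251 probe sets were used more and 64 less while 185 of the 296 genes had a relative change below 0. Signal from a changed neighbouring gene, the nearest with a tested level, was argued against by an odds ratio of 0.892 (95% interval 0.605 to 1.29) within each direction, where a doubling would be needed. With directions pooled the odds ratio was 0.587 (95% interval 0.403 to 0.835). That value mixes the directions and is no evidence by itself. Among uncalled genes 9.85% had such a neighbour where the probe set was higher and 30.7% where it was lower. Between shGFP and uninfected cells, the probe sets called had 2.52 times the median spread of all probe sets (95% bootstrap interval 2.05 to 3.23, n = 78), so noisy probe sets judged by the spread of their whole gene may account for those calls. The corresponding ratios were 1.27 for LL-sh4 against shGFP and 1.05 against uninfected, and an effect of the hairpin on splicing stays open there as a hypothesis, beside effects of the hairpin on other targets, which were not tested.

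The second pattern was the set of the 10 largest rises in LL-sh4 against shGFP cells, from CCL1 to TNFSF4, some of which are also genes of mature dendritic cells. RNA from dendritic cells or monocytes was tested with 19 abundant transcripts of these cells. They had a median relative log2 change of 0.40 (quartiles 0.17 to 0.64), which met the bound set against this source. The lowest relative change was 0.040 (LYZ), so all lay above the median gene, and 2 were up by at least 1 relative to it (CCL22 at 1.58 and SPI1 at 1.05). Without that shift LYZ (5.70 in LL-sh4 against 5.78 in shGFP), LGALS2 (5.70 against 5.77) and MS4A6A (5.71 against 5.72) were lower in LL-sh4 cells. The levels of CST3 (6.04), LYZ (5.70), CD1C (5.82) and TYROBP (6.08) in LL-sh4 cells lay under the dim threshold, while 6 of the 19 lay above it, CTSB (9.92), CTSS (9.27) and LAMP3 (9.16) among them, against 3 in shGFP cells, and 9 of the 19 are also in the fixed marker list. Isolation of CD4+ T cells would remove most such cells. Without both narrow arrays the 10 genes had a median of 2.92 (lowest 2.55, highest 4.87), against 2.94 with all arrays. The rises were thus also present on LL-sh4 replicate 1. However, the 10 genes were chosen among those whose LL-sh4 arrays both lay apart from both shGFP arrays. A rise on replicate 1 was therefore largely given by the choice, and the check does not decide on the narrow LL-sh4 array as a source. Most of the 19 transcripts lay under the dim threshold, where changes may be understated. Their test therefore does not decide on RNA from dendritic cells or monocytes, and that source stays open. An effect of the hairpin, on HNRNPLL or on another target, and a difference in the state of the cultures also stay open and may each account for the rises.

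The third pattern was that LL-sh4 replicate 2 and uninfected replicate 2 departed from replicate 1 in the same way, with r = 0.81 across genes. Scaling of whole arrays was argued against as the source of this correlation, since r was 0.82 after quantile normalization. A trend with signal level or with the number of probe sets was argued against by r = 0.75 once such trends were removed. The correlation ignores an offset of a whole array, and both groups had one. The median difference of replicate 2 minus replicate 1 was -0.31 in LL-sh4 and -0.28 in uninfected cells, against 0.035 in shGFP cells. A batch, culture day or donor that these arrays share is a candidate explanation that stays open, because the labels give none of them. No biological explanation was tested.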

How the results depend on the processing

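The one setting chosen only after the result was seen was leaving out both arrays of narrow spread together. Counts, the HNRNPLL changes, named genes and gene lists were recomputed under each alternative. Of 252 counts 140 stayed within 1.5 times and 112 moved further. Of 30 values of HNRNPLL 25 stayed past the threshold and 5 lost it with the direction kept. Of 2869 values of other named genes 2484 kept direction and side of the threshold, 278 lost it, 102 gained it and 5 turned. Of 476 list results called at first 373 stayed and 103 were lost. The 5 that turned are the PTPRC gene level in shGFP against uninfected, which lies close to 0. It was -0.012 with the 75th percentile filter, -0.086 with the median of probe sets and -0.068 without both narrow arrays, and ran from -0.068 (without uninfected replicate 2) to 0.070 (without uninfected replicate 1) with 1 array left out, with -0.0056 without shGFP replicate 1. Comparisons of single probe sets outside genes were not run under alternatives, because probe sets could be assigned to genes. No background level was used here, and changes to or from levels under the dim threshold may be understated. The cause of each difference below was not tested unless one is named. Counts are given in the order LL-sh4 against shGFP, LL-sh4 against uninfected, shGFP against uninfected.

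With array medians subtracted the genes past the threshold were 3505, 3340 and 27, the F test called 3513, and 2532 passed the same way against both controls. With quantile normalization these were 4246, 4353, 119, 4592 and 3327, exon usage changed in 557, 560 and 220 genes, and 4 spliced transcripts passed against shGFP. Without the dim filter these were 1143, 1016, 0, 880 and 685 (where limma gave 0, the main count was 7), HNRNPLL against uninfected was -0.72 (adjusted p = 0.092), 15 lists passed between the controls, exon usage changed in 2500, 2062 and 2366 genes, and 4, 8 and 2 spliced transcripts passed. With the 75th percentile filter exon usage changed in 73, 56 and 8 genes, of fewer tested, and 1 PTPRC probe set and 1 spliced transcript passed against each control. The mean of PTPRC probe set 2373878 over all arrays lies under this filter, so the probe set that passed there was another. With the median of probe sets 3 genes passed between the controls, 825 passed against both, and HNRNPLL against uninfected was -0.26 (adjusted p = 0.58). With trend and robust moderation 29 genes passed between the controls. Without moderation, where few residual degrees of freedom are left, 96, 180 and 0 genes passed, the F test called 38, 85 passed against both, HNRNPLL was -1.16 (adjusted p = 0.14) and -0.82 (adjusted p = 0.25), and 5 lists passed between the controls. At an adjusted p under 0.10 15 genes passed between the controls, and with only those groups in the fit 793 did. An estimated correlation left 0, 0 and 0 lists past the threshold, and fry also 0, 0 and 0. With the splicing index 31, 41 and 0 genes changed usage, with 1 PTPRC probe set (2373878) and 1 spliced transcript against each control. Among genes above the median level 144, 142 and 48 changed usage, of fewer tested.

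Without both narrow arrays, 5848, 5612 and 1916 genes passed, the F test called 6638, 4528 passed against both controls, exon usage changed in 1351, 1602 and 321 genes, 5 PTPRC probe sets passed against shGFP and 1 between the controls, and 6 spliced transcripts passed against shGFP. That fit took the spread from the 2 shGFP arrays alone, the pair with the smallest SD of differences (0.11, against 0.29 for LL-sh4 and 0.22 for uninfected). Its counts therefore cannot be read as stronger differences. With 1 array left out, a lone array is assumed to vary like the other groups. The genes past the threshold then ran from 779 to 4473, from 1329 to 2725 and from 5 to 793, the F test from 1251 to 4627 and the genes passing against both controls from 606 to 2217. Gene lists ran from 9 to 11, from 11 to 12 and from 1 to 3, and genes with changed usage from 67 to 1002, from 92 to 548 and from 12 to 239. HNRNPLL ran from -1.30 to -0.98 and from -1.0 to -0.65, PTPRC probe sets from 2 to 3, from 2 to 2 and from 0 to 0, and spliced transcripts from 1 to 3, from 3 to 4 and from 0 to 1.

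With the replicate block 3848, 3123 and 820 genes passed, the F test called 4576, 2217 passed against both controls, and exon usage changed in 478, 395 and 194 genes. The blocked fit ended the list calls of naive and resting genes against shGFP (adjusted p = 0.0998) and against uninfected (0.052), of oxidative phosphorylation against shGFP (0.064) and of SR proteins between the controls (0.075), and no other list call. The deviations of same-numbered arrays correlated at -0.088 for LL-sh4 and shGFP, 0.81 for LL-sh4 and uninfected and -0.075 for shGFP and uninfected, so the numbers were not taken to pair the arrays.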

Other observations

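All tests in this part were chosen only after the result was seen, except the test of KLF2 target genes. The families described were chosen after the largest changes had been seen.

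Of genes of antigen presentation on HLA class II, all 9 measured members rose in LL-sh4 against uninfected cells (camera adjusted p = 6.9e-08, adjusted p = 0.24 with an estimated correlation), among them HLA-DOB (1.66), HLA-DPB1 (1.08), HLA-DRA (0.86) and CIITA (1.01), the transactivator of these genes. Against shGFP cells 3 rose (camera adjusted p = 1.9e-06, adjusted p = 0.40 with an estimated correlation), HLA-DOB (1.28), HLA-DRA (1.15) and HLA-DPB1 (0.87), and 9 did so after quantile normalization and also after subtraction of array medians. Between the controls the family had a median of 0.17 (camera adjusted p = 0.026, adjusted p = 0.79 with an estimated correlation), with 0 members past the threshold in limma and 3 with an unadjusted p under 0.05. Of transcripts of antigen-presenting cells, VCAN rose by 1.67 against shGFP, while AIF1 of the same marker list fell. The 19 dendritic cell and monocyte transcripts had a median of 0.40 and ran from 0.040 for LYZ to 1.58 for CCL22, with SPI1 at 1.05 and CCL17 at 0.92. In shGFP cells CCL22 (5.45), SPI1 (3.86) and CCL17 (5.77) lay under the dim threshold of 6.55. SPI1 (4.78) also did so in LL-sh4 cells. Replication-dependent histone genes fell in 4 of 8 against shGFP (camera adjusted p = 0.048, adjusted p = 0.67 with an estimated correlation) and in 3 against uninfected (camera adjusted p = 0.012, adjusted p = 0.53 with an estimated correlation). Without H1-1, which prompted the choice of this family, 3 and 2 of 7 fell, H2BC15 (-1.25 and -1.72) and H1-4 (-0.47 and -0.56) among them, and the family passed in neither contrast (camera adjusted p = 0.18 and 0.087). After quantile normalization 2 histone genes were higher and 5 lower against shGFP, and 1 and 5 against uninfected.

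Proteasome subunit genes fell in 6 of 35 against shGFP (camera adjusted p = 0.0058, adjusted p = 0.73 with an estimated correlation) and in 1 of 35 against uninfected (adjusted p = 0.50). Quantile normalization gave 12 lower against shGFP, and 2 higher and 7 lower against uninfected. Between shGFP and uninfected cells 0 of the 35 passed in limma (8 with an unadjusted p under 0.05), with a median of 0.17 and camera adjusted p = 0.0011 (adjusted p = 0.79 with an estimated correlation). Of 13 aminoacyl-tRNA synthetase genes 1 rose and 3 fell against shGFP (camera adjusted p = 0.094) and 4 fell against uninfected (camera adjusted p = 0.0026, adjusted p = 0.55 with an estimated correlation), with 5 and 8 lower after quantile normalization. Between shGFP and uninfected cells 0 of the 13 synthetase genes passed in limma (2 with an unadjusted p under 0.05), with a median of -0.18 and camera adjusted p = 0.0039 (adjusted p = 0.79 with an estimated correlation). After quantile normalization 3 of them were lower in that contrast.

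PHGDH, PSAT1 and ASS1 fell in LL-sh4 against uninfected cells, and a hypothesis is that the fall runs over the other genes of serine, glycine, asparagine and arginine synthesis. The other 12 members had a median relative log2 change of -1.02 (quartiles -1.14 to -0.53), in the direction of the hypothesis. ASNS, among them, had already been seen to fall in the endoplasmic reticulum stress list. The test of the whole family given next includes PHGDH, PSAT1 and ASS1, which prompted the choice. In the whole family 12 of 15 fell against uninfected (camera adjusted p = 5.4e-12, adjusted p = 0.24 with an estimated correlation) and 10 against shGFP (camera adjusted p = 1.4e-05, adjusted p = 0.50 with an estimated correlation), with SHMT2 at -1.13 and -0.79, ALDH18A1 at -1.38 and -1.29 and CBS at -1.62 and -0.67, while MTHFD2 stood at 0.13 and 0.25. Between the controls 1 member, ASS1, passed in limma (6 with an unadjusted p under 0.05) and the median was -0.39 (camera adjusted p = 9.7e-12, adjusted p = 0.79 with an estimated correlation). Quantile normalization gave 6 lower members between the controls and subtraction of array medians 3. Part of the fall against uninfected cells may therefore belong to infection and not to the LL-sh4 hairpin.

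CCL1, TNFSF4, TNFRSF18 and TNFRSF4 rose in LL-sh4 cells, and a hypothesis is that the rise runs over the other chemokines and TNF superfamily genes. The other 33 measured members had a median relative log2 change of 0.70 (quartiles 0.27 to 1.14) against shGFP, in the direction of the hypothesis. Some of them, such as CCL20, CCL5, FASLG and TNFRSF9, had already been seen to rise in the lists of this contrast. The value is therefore not independent support. The tests of whole families given next include the genes that prompted the choice. Chemokines rose in 4 of 6 (camera adjusted p = 2.8e-08, adjusted p = 0.22 with an estimated correlation) and TNF superfamily genes in 13 of 31 (camera adjusted p = 4.0e-14, adjusted p = 0.22 with an estimated correlation), with LTA at 1.82, TNFSF9 at 1.94 and TNFSF10 at 1.16. Against uninfected cells 4 chemokines rose and 1, CXCL8 (-0.65), fell, and 16 TNF superfamily genes rose. After quantile normalization 23 TNF superfamily genes were higher and 1 lower against shGFP.

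KLF2 fell in LL-sh4 cells against both controls, and a hypothesis is that T cell egress genes named as its targets fall with it. The 4 measured had a median of 0.033 (quartiles -0.53 to 0.51) against shGFP. That value meets the bound set in advance against the hypothesis, a median above -0.25, but the members went both ways, with S1PR1 at -0.87 (adjusted p = 0.0029) and S1PR4 at -0.42 (adjusted p = 0.028) and with CD52 at 0.49 and ITGB7 at 0.59. A median near 0 over such members decides nothing, a reading added after the value was seen, and the hypothesis stays open. Against uninfected cells, where no bound was set, the 4 genes had a median of -0.247, with 0 higher and 1 lower in limma. The lower one was S1PR4 (-0.61, limma adjusted p = 0.025), while S1PR1 stood at -0.53, CD52 at 0.16 and ITGB7 at 0.03.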
